A study of Rattus norvegicus with 6 samples.

How the data were processed

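Gene expression was measured in cultured cortical neurons from Sprague-Dawley rat embryos of day 18, grown for 3 days, on 6 one-colour Affymetrix arrays. Per the labels, 3 arrays held RNA of untreated neurons and 3 held RNA of neurons given 10 nM C1q for 3 h. The labels number the arrays 1 to 3 within each group and do not state whether the numbers mark separate cultures or embryos.

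The deposited value table gives 1 intensity on a linear scale for each of 29215 probe sets on each array, and the summarisation and normalization behind these values are not given in the sources used here. The deposited intensities ran from near 0 to 20239, with array medians between 147 and 155. Total RNA was extracted with a column kit and biotin-labelled cRNA was prepared by the standard Affymetrix protocol, per the labels' protocols. All 6 value columns were used. No probe set carried a control name, so control probe sets were not removed by name. No detection calls or background levels were used, so signal over background is unknown.

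Probe sets were named from the platform annotation, with symbols updated through gene identifiers to a RefSeq table of the GRCr8 assembly, which changed 0 symbols. Exactly 1 gene was named for 15310 probe sets, of which 15279 matched the RefSeq table. Several genes were named for 323 probe sets and none for 13582, and no gene is reported from either kind. In the table, 319 probe sets shared identical values with at least 1 other probe set. A gene was represented by its single-gene probe set of highest mean log2 value over all 6 arrays.

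Values were analysed as log2(intensity + 16). The array medians differed by at most 0.070 on this scale, under a limit of 0.1 fixed beforehand, so the values were used as deposited. Fold changes on this scale understate the change of dim genes. The 60% of probe sets with the highest mean were tested, a threshold at an intensity of 94.4. This left 17529 probe sets, 10302 of them naming 1 gene, 121 several and 7106 none, and 9652 genes. C1q-treated and untreated arrays were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over the 17529 probe sets, with calls at an adjusted p under 0.05. Intervals are 95% intervals of the same limma fit. The number of arrays limits the precision. The p-values measure the spread between these arrays, which may be technical.

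Gene lists were compared with the remaining genes by camera in limma with a preset correlation of 0.01, on 1 probe set per gene, for lists with at least 5 tested members. Of 31 lists, 29 were tested, and the microglial and endothelial marker lists had 3 tested members each. The lists held 689 symbols, of which 600 were matched and 482 tested. They covered cholesterol synthesis, cholesterol handling, neurotrophins and growth factors, immediate early genes, MAP kinase feedback, NF-kB and cytokine genes, interferon response, complement, proposed C1q receptors, presynaptic genes, postsynaptic genes, axon guidance, cytoskeleton, apoptosis, oxidative stress, protein folding stress, hypoxia and glycolysis, described targets of the let-7 microRNA, ion channels, ribosomal proteins, the respiratory chain and proliferation. Marker lists covered excitatory neurons, inhibitory neurons, astrocytes, the oligodendrocyte lineage, microglia, radial glia, endothelium, mural and meningeal cells, and blood.

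The rule for named genes was fixed before the data were examined, as were the lists, the tests between the groups and all but 2 of the alternatives. It took the 12 genes per direction with the largest change among those that passed and whose groups did not overlap, filled up by smallest unadjusted p where fewer passed. It added up to 4 genes of smallest unadjusted p from each list and 17 genes chosen by name.

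The procedure was tested on simulated data. Changes of known size were added to the deposited values of 200 of the 17529 probe sets. The limma fit recovered 20% of changes of 0.25 log2, 86% of 0.5, 96% of 0.75 and 98% of 1, with 4 false calls. With independent noise in place of the deposited spread it recovered 26%, 74%, 84% and 90%, with 7 false calls. Both simulations changed 200 probe sets at once, which loosens the Benjamini-Hochberg cutoff for each of them. They therefore do not give the recovery of a lone change, which would be lower. Alternatives covered quantile normalization, median centring, the filter, the pseudocount, the variance model, array weights, the replicate number as a block, leaving out each array, the correlation in camera, fry, and the mean of a gene's probe sets. Using the main component of the within-group spread as a covariate and leaving out untreated arrays 1 and 2 together were chosen after seeing the data.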

Results

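Transcript levels of rat cortical neurons were measured on 3 arrays of untreated cells and 3 arrays of cells given the complement protein C1q at 10 nM for 3 h. Median intensities were 150, 155 and 150 on untreated arrays 1 to 3 and 149, 147 and 150 on C1q arrays 1 to 3. Log2 values correlated between arrays, across probe sets, at 0.989 to 0.996. The comparison asks which neuronal transcripts differ after a short exposure to C1q, a subject named in the series title together with neuroprotection.

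No gene tested was called as changed after 3 h of C1q by the limma test, which recovered 20% of added changes of 0.25 log2. Genes below the filter were not tested. A fit with array weights, which rested mostly on untreated array 3, called 447 probe sets. The lists of neurotrophin, immediate early, cholesterol and synaptic genes had median log2 fold changes between -0.02 and 0.01. Ntf3, which encodes neurotrophin-3, had an intensity of 228 ± 19.2 (SD, n = 3) in untreated and 220 ± 9.90 (SD, n = 3) in C1q-treated neurons. Fos, an immediate early gene, read 229 ± 14.5 untreated and 207 ± 14.3 after C1q (SD, n = 3 each). Or1f26, an olfactory receptor gene, lay near the filter intensity of 94.4 in untreated neurons. Among genes taken by the fixed rule whose groups did not overlap, its fold change was the highest. It read 103 ± 23.6 against 157 ± 21.3 (SD, n = 3 each) and did not pass. Nor did the beta-globin gene Hbb, at 970 ± 83.2 against 1155 ± 67.3 (SD, n = 3 each).

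Of 17529 probe sets tested with limma, 0 were higher and 0 lower after C1q at an adjusted p under 0.05, and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 437 probe sets, 109 higher and 328 lower, where 876 is the average without any difference. Such a count varies widely, as other splits of the 6 arrays into groups of 3 gave 294 to 3263. With the replicate number as a block limma called 9 higher and 0 lower. With array weights it called 130 higher and 317 lower, and without untreated array 2 it called 28 higher and 10 lower. Of those 447 probe sets 123 named exactly 1 gene, among them 17 of the 24 genes named for the smallest p, such as Slc6a4, Hbb and Or1f26, and 7 other named genes, C1r, Cntf, Cox5a, Fabp7, Ndufv2, Npy and Rrm2. No gene was named for 310 of the 447 or for any of those 38, and 24 of the 28 higher ones had IDs in 1 close run, with only 18 distinct sets of values among the 28. The 95% interval of the fold change lay within 1.5-fold for 98.8% of probe sets and within 2-fold for 99.9%. C1q and untreated arrays did not overlap for 1002 probe sets, or 5.72%, where chance gives 10% on average. Means were lower after C1q for 63.3% of probe sets, a share of 49.2% with quantile normalization and 44.6% with median centring, so that the tilt depended on the scaling.

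None of the 12 genes named for the smallest unadjusted p with a higher mean after C1q passed. Besides Hbb, Hbb-b1 read 848 ± 76.8 untreated and 987 ± 49.8 after C1q, and Hba-a3, an alpha-globin gene, read 895 ± 40.2 and 1007 ± 50.8 (SD, n = 3 each). The histone genes H2ac4, Hist1h2bq and Hist1h2bg had fold changes of 1.13, 1.12 and 1.12. Globin and histone genes have close copies whose RNA one probe set can bind, so their individual values are uncertain. Nherf2, a scaffold protein gene, had a fold change of 1.19, and Lin7a, which encodes a scaffold protein of cell junctions, 1.15. Fold changes were 1.38 for Hcls1, a dim gene at 87.6 untreated, 1.12 for Mettl27 and 1.52 for the pseudogene LOC366310. The log2 fold changes of these 12 genes lay between 0.16 and 0.60, and LOC366310 read 324 on untreated array 1 against 585 and 760 on the other untreated arrays.

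The 12 genes named for a lower mean did not pass either, and their groups did not overlap. Their choice by smallest unadjusted p on these same arrays favours both such separation and intervals clear of no change. Slc6a4, the serotonin transporter gene, read 341 ± 13.9 untreated and 281 ± 3.23 after C1q (SD, n = 3 each), a fold change of 0.831 with a 95% interval of 0.748 to 0.923. Rasl2-9 read 866 ± 28.2 and 741 ± 28.1, and Cpt2, a mitochondrial enzyme of fatty acid oxidation, 250 ± 22.6 and 203 ± 15.8 (SD, n = 3 each). Gabrd, the delta subunit gene of the GABA-A receptor, had a fold change of 0.822, Cpn1 0.796, Cldn22 0.782 and Zdhhc18 0.875. Fold changes were 0.878 for Setsip, 0.898 for the ribosomal protein gene Rpl3, 0.909 for Tent5d, 0.914 for the histone gene H3f3b and 0.906 for Efhd2.

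**Figure D1:**
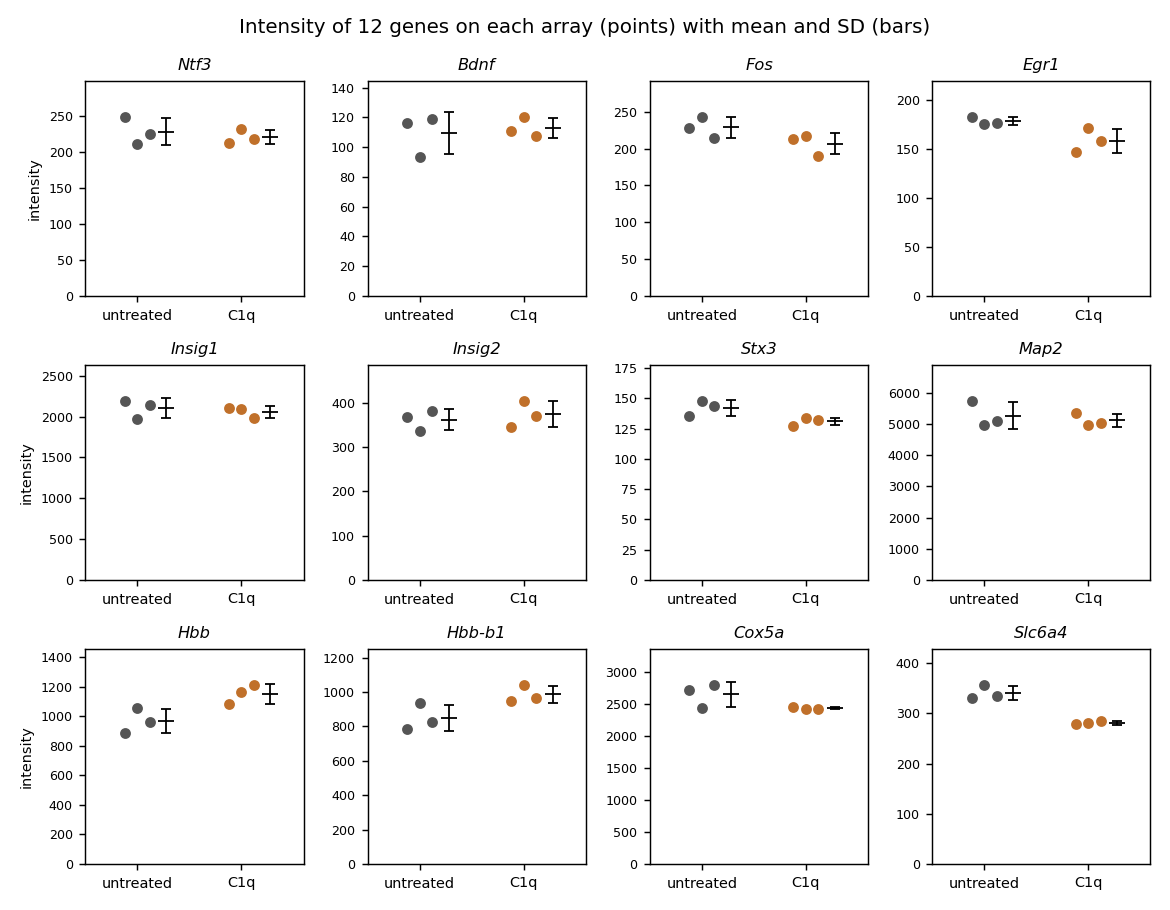
Intensity (linear axis from 0) of 12 genes on each of the 6 arrays, with points for the arrays and bars for the mean and SD of the 3 untreated and 3 C1q arrays. Ntf3, Bdnf, Insig1, Insig2 and Map2 overlap between groups, while the arrays of Hbb, Hbb-b1, Egr1, Stx3 and Slc6a4 separate without passing the test over all probe sets.

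None of 17 tested neurotrophin and growth factor genes passed, over all genes or adjusted over the list alone, with 10 means higher and 7 lower, a balance of 13 to 4 with quantile normalization and 14 to 3 with median centring. Bdnf, which encodes brain-derived neurotrophic factor, read 109 ± 14.2 untreated and 113 ± 6.76 after C1q (SD, n = 3 each), a fold change of 1.03 with a 95% interval of 0.869 to 1.22. Bdnf lay near the filter intensity of 94.4 with an unknown share of background, so this interval may not bound a change of its mRNA. The fold change of Ntf3 was 0.970, with an interval of 0.852 to 1.11. Cntf, the ciliary neurotrophic factor gene and also a dim one, read 133 ± 18.4 and 160 ± 2.72 (SD, n = 3 each), and the arrays of both groups did not overlap. Vgf had a fold change of 0.937.

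None of 25 immediate early genes and CREB targets passed, with 7 means higher and 18 lower. The balance was 10 to 15 with quantile normalization and 13 to 12 with median centring. Egr1 read 178 ± 3.90 untreated and 158 ± 12.3 after C1q (SD, n = 3 each), a fold change of 0.896 with a 95% interval of 0.782 to 1.03, and Fos had a fold change of 0.909 with an interval of 0.797 to 1.04. Arc, below the filter on dim probe sets, read 79.8 ± 8.07 and 66.8 ± 2.36 (SD, n = 3 each), and Creb1 had a fold change of 0.986. Of 18 MAP kinase feedback genes, which the pathway itself induces, 0 passed and 9 means lay on either side. Their balance was 10 higher to 8 lower with quantile normalization and 13 to 5 with median centring. Fold changes were 1.06 for Spry2 and 1.07 for Etv5.

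The cholesterol lists showed no gene that passed. Of 20 tested synthesis genes 6 means were higher and 14 lower, a balance of 11 to 9 with quantile normalization or median centring, and the highest and lowest log2 fold changes were 0.03 and -0.06. Insig1, which holds back processing of the sterol regulatory element binding proteins, read 2104 ± 119 untreated and 2061 ± 71.4 after C1q (SD, n = 3 each). Its 2 probe sets were of opposite sign. Insig2 read 362 ± 23.9 untreated and 374 ± 29.3 after C1q (SD, n = 3 each). Of 16 handling genes 6 means were higher and 10 lower, a balance of 10 to 6 with either rescaling, with fold changes of 0.929 for the lipoprotein receptor gene Scarb1 and 1.06 for Cyp46a1, the neuronal cholesterol hydroxylase. Ch25h, the cholesterol 25-hydroxylase gene, and Lpl, the lipoprotein lipase gene, lay below the filter, at 37.2 ± 1.76 untreated and 32.8 ± 8.05 after C1q, and at 78.9 ± 8.78 and 85.7 ± 11.5 (SD, n = 3 each).

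The inflammatory and complement genes tested did not pass. Most members of these lists lay below the filter and were not tested, such as Tnf, Il6, Isg15 and C3. The array held 28 NF-kB and cytokine, 24 interferon response and 16 complement genes of the lists. Of 13 NF-kB and cytokine genes 6 means were higher and 7 lower, with fold changes of 0.815 for the chemokine gene Ccl4, a dim gene at 108 untreated, and 1.06 for the NF-kB inhibitor gene Nfkbia. Of 7 interferon response genes 2 means were higher and 5 lower. Of 7 complement genes 3 means were higher and 4 lower. C1r, a dim gene that encodes a protease of the C1 complex, read 121 ± 5.39 untreated and 100.1 ± 6.83 after C1q (SD, n = 3 each). Clu, which encodes clusterin, read 484 ± 25.6 and 442 ± 2.22 (SD, n = 3 each). Of 12 proposed C1q receptor and partner genes 2 means were higher and 10 lower, with fold changes of 0.900 for Ptx3 and 0.965 for C1qbp. The balance of this list was 4 to 8 with quantile normalization and 6 to 6 with median centring. With either rescaling the higher and lower means numbered 8 and 5 for NF-kB and cytokine, 3 and 4 for interferon response and 4 and 3 for complement genes.

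No gene of the neuronal lists passed. Of 25 presynaptic genes 10 means were higher and 15 lower, with fold changes of 0.928 for Stx3, a plasma membrane syntaxin gene, 0.994 for Syn2 and 1.01 for Syn3. Of 25 postsynaptic genes 13 means were higher and 12 lower, with fold changes of 1.05 for Shank1 and 0.934 for Homer2. Of 26 axon guidance genes 12 means were higher and 14 lower, with all log2 fold changes between -0.06 and 0.06. Of 23 cytoskeleton genes 10 means were higher and 13 lower, and Map2, a dendritic microtubule protein gene, read 5271 ± 421 untreated and 5116 ± 207 after C1q (SD, n = 3 each). Of 23 ion channel genes 11 means were higher and 12 lower. With median centring the higher and lower means numbered 14 and 11 for presynaptic, 18 and 7 for postsynaptic, 21 and 5 for axon guidance, 16 and 7 for cytoskeleton and 17 and 6 for channel genes. After quantile normalization they numbered 14 and 11, 16 and 9, 20 and 6, 13 and 10, and 16 and 7 in that order. The reference genes Actb and Gapdh had fold changes of 1.01 and 1.02, and 11 of 16 tested Gapdh probe sets shared the sign.

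Stress and survival genes did not pass either. Means were higher and lower for 7 and 13 of 20 apoptosis genes, 5 and 12 of 17 oxidative stress genes, 5 and 18 of 23 protein folding stress genes, and 6 and 17 of 23 hypoxia and glycolysis genes. With median centring the higher means outnumbered the lower in each of these 4 lists. Hmox1, the heme oxygenase gene and a dim one at 107 untreated, had a fold change of 0.891. Fold changes were 0.937 for Sod1, the cytosolic superoxide dismutase gene, and 0.959 for the stress transcription factor gene Atf4. Of 15 described let-7 targets 6 means were higher and 9 lower. Fold changes were 0.936 for Arid3b, 0.956 for Cdk6, 0.966 for Cdc25a and 1.04 for Mycn. Of 22 proliferation genes 10 means were higher and 12 lower. With median centring the higher and lower means numbered 8 and 7 for let-7 targets and 13 and 9 for proliferation genes. After quantile normalization they numbered 7 and 8, and 12 and 10.

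Camera called 2 of 29 lists. The 25 respiratory chain genes lay lower relative to other genes, with adjusted p = 0.0120 and 20 of 25 means lower, at a median log2 fold change of -0.039, which was -0.018 with 17 lower after quantile normalization and -0.013 with 18 lower after median centring. This call was lost with an estimated correlation (adjusted p = 0.932). The means were 2654 ± 192 and 2434 ± 17.4 for Cox5a and 1266 ± 79.7 and 1169 ± 32.5 for Ndufv2, untreated and after C1q (SD, n = 3 each), and no member passed, over all genes or adjusted over the list alone. Camera called the 5 blood markers as higher relative to other genes, with adjusted p = 0.000196 and 3 means higher and 2 lower, or 5 and 0 with either rescaling, and 2 members, Hbb and Hbb-b1, passed adjusted over the list alone, with a smallest adjusted p of 0.0167. With an estimated correlation the adjusted p of the blood list was 0.932 as well. The median and mean of that list were 0.02 and 0.09, and the log2 fold changes of the other members were -0.02 for Alas2, 0.02 for Ppbp and -0.02 for Pf4, which was named after its value was seen. Neither call held with quantile normalization (adjusted p = 0.0844 and 0.0627). Fry, which asks whether a list moves one way at all and not whether it differs from other genes, gave adjusted p = 0.975 for both. Over all alternatives the adjusted p ran from 1.06e-07, with a single untreated array left, to 0.975 for the respiratory chain and from 2.01e-08, without untreated array 2, to 0.975 for blood. The respiratory chain call was also lost with median centring (adjusted p = 0.285) and without untreated array 3 (0.768), C1q array 2 (0.173) or C1q array 3 (0.0642), and the blood call without untreated array 1 (0.197).

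The other 27 tested lists were not called, though axon guidance and cytoskeleton genes were without untreated array 1 and ribosomal protein genes without C1q array 1, and no member passed adjusted over the list alone in any list but blood. Ribosomal protein genes had 8 means higher and 22 lower of 30, with camera's adjusted p at 0.419, and 14 and 16 with quantile normalization. All 8 oligodendrocyte lineage markers had lower means, at a median log2 fold change of -0.04, and 6 of 8 did with quantile normalization or median centring. Higher and lower means numbered 3 and 5 for excitatory neuron markers, 3 and 7 for inhibitory neuron markers, 7 and 4 for astrocyte markers, 4 and 6 for radial glia markers, and 2 and 6 for mural and meningeal markers. After quantile normalization they numbered 4 and 4, 3 and 7, 7 and 4, 6 and 4, and 4 and 4 in that order, and after median centring 4 and 4, 4 and 6, 7 and 4, 7 and 3, and 3 and 5. The inhibitory neuron genes Gad1 and Npy had fold changes of 0.937 and 0.932. The 3 microglial and 3 endothelial markers tested each had 1 mean higher and 2 lower. Camera compares the mean test statistic of a list with that of the other genes. The 9652 genes lay lower as a whole, with 6085 negative log2 fold changes and a median of -0.0157. A list can therefore lie higher than the other genes though its own values are mostly negative. A negative median went with a camera direction of up for 9 lists. These were cholesterol handling, presynaptic, axon guidance, cytoskeleton, apoptosis, let-7 target, ion channel, proliferation and excitatory neuron genes. The mean was positive for axon guidance and ion channel genes, and for postsynaptic and astrocyte genes it was negative beside a positive median.

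**Figure D2:**
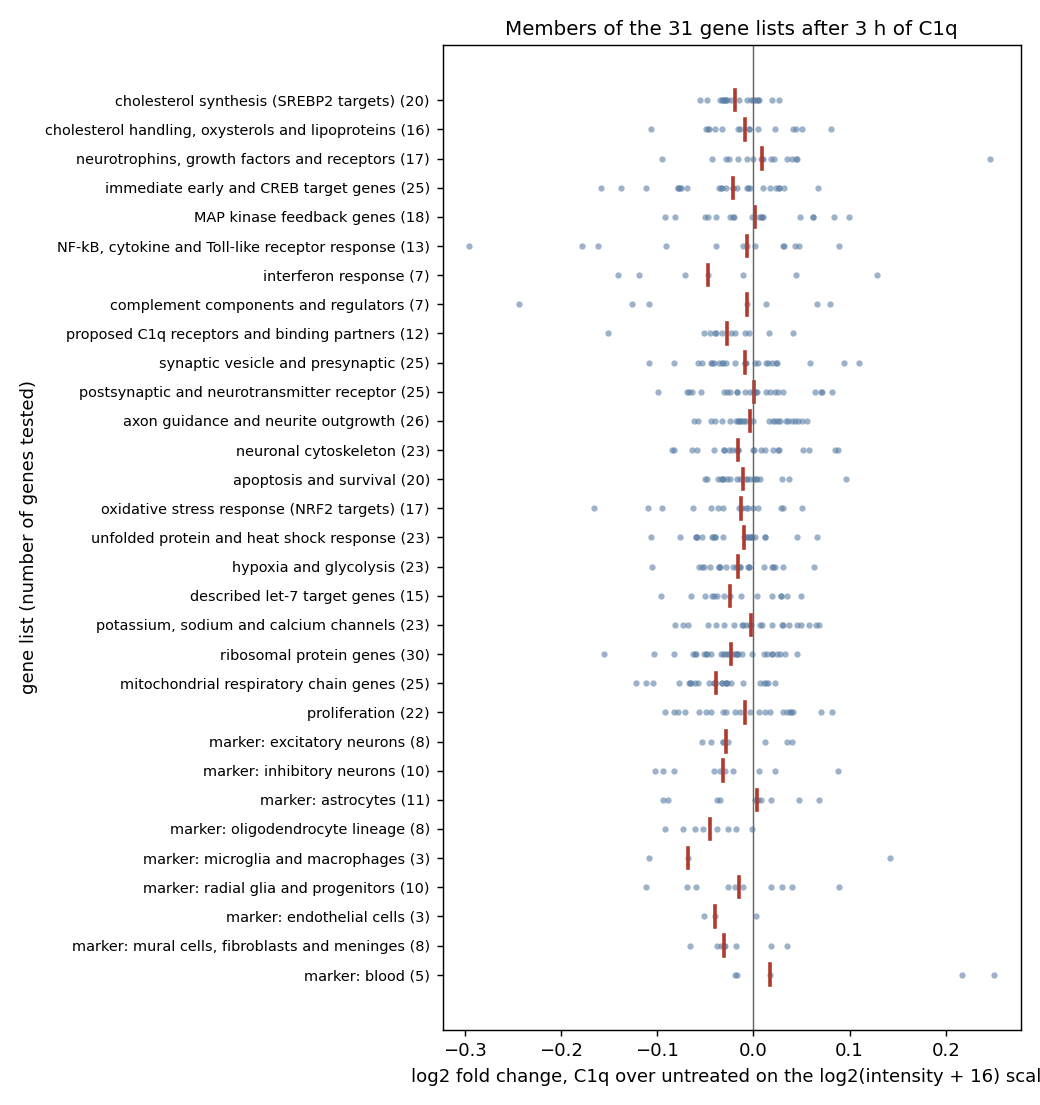
Log2 fold change of C1q over untreated (horizontal axis, log2 scale) for each tested member (points) of the 31 gene lists (vertical axis, with the number tested), with the list median as a red bar. All list medians lay within 0.068 of 0, and the points farthest to the right in the blood list are Hbb and Hbb-b1.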

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

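Leaving out untreated arrays 1 and 2 together and the within-group component as a covariate were chosen after seeing the data. No probe set was called, in either direction, with quantile normalization, median centring, the brightest 40%, a pseudocount of 1 or 64, no intensity trend, robust variance or the component covariate. Counts of higher and lower probe sets were 130 and 317 with array weights and 46 and 16 without untreated arrays 1 and 2. The latter fit set 1 untreated array against 3, took its spread from the C1q arrays alone and assumed that the lone array varies like them. The array weights were 0.362, 0.335 and 5.51 for untreated arrays 1 to 3, so that fit also rested mostly on untreated array 3. All 38 calls made without untreated array 2 were among the 447 made with array weights, as were 59 of the 62 made without both arrays, an overlap that such weights favour. Leaving out each array in turn gave 0 to 28 higher and 0 to 10 lower, with every call made without untreated array 2. Without the filter 1 probe set was lower and 0 higher. The cause of these differences was not tested.

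The number of lists called by camera was 0 with quantile normalization and with an estimated correlation, 1 with median centring, 1 with the brightest 40%, where fewer than 5 blood markers were left, and 1 to 3 when each array was left out. Fry, which tests each list against no change and not against other genes, called 0. The cause was not tested.

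With the replicate block, 9 probe sets were higher and 0 lower, and it changed no list call. Deviations from the group means correlated, across probe sets, at 0.014, -0.453 and -0.134 for same-numbered arrays, and no untreated array correlated best with its own number, so the numbers were not taken to pair the arrays.

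Of values under the alternatives, 17 of 449 passed for the 24 genes named for smallest p, all 17 with array weights, with 0 changes of sign, which their choice by p on these arrays favours. For the other 126 named genes 7 of 2358 passed, all with array weights, and 87, in 36 genes, changed sign. Changes of 0.25 log2 lay mostly below what the 6 arrays could detect, and signal over background is unknown.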

Other observations

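A few genes, singled out after their values were seen, read low on untreated array 1. Rpph1, a noncoding RNA gene, read 4414 on untreated array 1 and 9339 to 10064 on the other 5 arrays. Terc, the telomerase RNA gene, read 215 on that array and 458 to 503 on the others, and Ccdc107, a protein-coding gene, read 1476 against 4062 to 4871. The C1q arrays of Ccdc107 all lay above the untreated ones, and it was called higher with the replicate block. LOC366310, a pseudogene, read 324 against 585 to 915, and its 3 tested probe sets were called higher with array weights. The median of these 4 genes on untreated array 1 lay at -1.14 log2 relative to the mean of the other arrays. The 1 probe set called without the filter, an unnamed one with ID 10700426, read 46.7, 34.4 and 51.2 on untreated arrays and 0.029, 0.03 and 0.016 on C1q arrays, with adjusted p = 0.00113 by limma, at intensities below the filter.

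Tests chosen only after the result was seen were those of quantile normalization, the histone genes, Alas2 and the probe set counts over other splits of the arrays. A lower yield of RNA without a poly(A) tail could lower Rpph1 and Terc on untreated array 1. It would lower replication-dependent histone genes as well, but their median difference over 16 genes was -0.0531 log2, ranging from -0.67 to 0.04, which argues against a loss of the whole class as large as that of Rpph1 and Terc. Of the 16 histone genes 8 read lowest on that array, so a smaller loss stays open. Histone probe sets can also bind RNA of close copies, so a loss confined to some noncoding RNAs stays open too, and no biological explanation was tested.

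Untreated arrays 1 and 2 stood at opposite ends of the main component of the spread within groups, which held 55.2% of that variance. An array-wide difference in the intensity distribution or a trend with intensity might produce it. The share stayed at 52.1% after quantile normalization and 51.8% after cyclic loess, so neither accounted for most of it. The labels give no difference between the untreated arrays, so no biological explanation was tested.

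The 4 tested globin genes, Hbb, Hbb-b1, Hba-a3 and Hbe1, had a mean log2 fold change of 0.24 after C1q, and Hbe1 was added after its values were seen. Array-wide scaling is unlikely to account for it, since the mean was 0.25 after quantile normalization. RNA of red blood cell precursors carried into the cultures in unequal amounts could raise globins, and an effect of C1q on these transcripts stays open as well. Alas2, an erythroid enzyme gene, had a log2 fold change of -0.0191 with a 95% interval of -0.22 to 0.19, but at 1.47 times the filter intensity it lay too near the floor to exclude such cells. These 2 explanations cannot be told apart with 3 arrays per group. No globin gene passed the limma test over all probe sets. Camera's call of the blood list was lost without untreated array 1 (adjusted p = 0.197). Chance and the values of that array therefore stay open as well.

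Splitting the 6 arrays in all 10 ways into groups of 3, with the limma fit, cannot give a share under 0.1, so these counts cannot exclude chance. With a real count of 0 higher and 0 lower, all 10 splits give as many by construction, so this says nothing of chance, and the highest other was 2. As many lists as the real 2 were called in 7 of the 10 splits, the real one included, the highest other being 6. With array weights, as many probe sets as the real 447 were called in 4 of the 10 splits, the real one included, the highest other being 997. At an unadjusted p under 0.05, 4 other splits exceeded the real 437, and the split that set untreated arrays 1 and 3 with C1q array 2 reached 3263, which points to a structure among the arrays other than the treatment.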
